A study of Mus musculus with 12 samples.

How the data were processed

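Poly(A) RNA of splenic B cells from 12 mice was sequenced as 100-bp read pairs on an Illumina HiSeq4000, per the labels' protocols. The spleens were made into single-cell suspensions, red cells were lysed, and live B220-positive cells were sorted; the labels give the sorted population as YFP-positive in YC and GFP-positive in BIC and pBIC. The submitters' processing notes name FastQC, STAR, featureCounts, edgeR and limma, and the mouse builds mm10 and GRCm38. The deposited values are raw counts of reads per gene, 1 table per library, with 50686 genes in each. Per the file headers they were made with featureCounts 1.5.0 over exons grouped by gene in the GENCODE M13 annotation, without the paired-end option, so that the mates of a pair were counted as separate reads, without a strand option, so that reads from a gene and its antisense partner cannot be told apart, and without multi-mapping reads. Reads that map equally well to near-identical copies are therefore missing from these counts, and genes with such copies are uncertain. The input folder named in the header of the YC 1 file follows another naming pattern than those of the other files, with the same settings, and the labels do not say whether that library was prepared or processed differently. Aligner versions and the filters applied to the reads are not given in the sources used here.

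Gene names and biotypes came from the GENCODE M21 annotation of the same build, which matched 50376 of the gene identifiers by name and 50462 by biotype; unmatched identifiers held at most 0.192% of the counts of a library. Coordinates are given on GRCm38, 1-based. Groups were taken from the sample titles, which name the model and a replicate number, and no sample was left out. The design text gives the number of mice per group. Sex was not given in the labels. Total counts per library ran from 33127283 to 47067627, and 3 counts, the limit that a count of 0 allows, correspond to 0.0637 to 0.0906 CPM. Intervals on shares of counts are 95% Wilson intervals, and intervals and limits cover counting error only, since PCR copies were not told apart, and they take the mates of a pair as independent, which makes them too narrow.

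The choices in this paragraph were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, edgeR's default expression filter by group (a minimum count of 10), a quasi-likelihood fit with robust dispersion and the quasi-likelihood F test, over all 12 libraries with 1 coefficient per group, and the Benjamini-Hochberg adjustment over the 17754 genes kept. A gene was called at an adjusted p under 0.05. The comparisons were BIC against YC, pBIC against YC and pBIC against BIC. The fit shared 1 estimate of the spread between groups, because 2 of them have 3 mice each. Standard errors (SE) of log2 fold changes were derived as the absolute log2 fold change divided by the square root of its F statistic. They therefore restate the test and add no separate information. Where 1 group has almost no counts, they are not a reliable measure of precision. CPM are counts scaled to a library total of 1e6 after TMM scaling.

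A set of 31 gene lists was fixed before the data were examined. They cover B cell states, lymphoma classifiers, cell growth and metabolism, antigen presentation, signalling, stress, and markers of other cells that a spleen sort could hold. Each was tested with camera (limma 3.58.1) on voom log2 CPM with the preset correlation of 0.01 between genes, adjusted over the 31 lists, and the number of members that rose or fell was counted from the edgeR test, over all genes and adjusted over the list alone. Camera was repeated with a correlation estimated for each list. With it 0 of 14 list calls held for BIC against YC, 1 of 12 for pBIC against YC (germinal centre genes) and 0 of 21 for pBIC against BIC, while 5, 7 and 8 of the 31 lists had an unadjusted camera p under 0.05; fry called 8, 12 and 21 lists. Fry was the other alternative. It tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Many lists share members with others, such as 13 of 28 B cell receptor signalling genes and 9 of 22 B cell identity genes, so their results are not independent. The proliferation and neutrophil lists share 0. Named genes were Prdm1, Ikbkb and Trp53, the 6 genes with the highest and the 6 with the lowest log2 fold change among called genes with a mean of at least 5 CPM over all 12 libraries and no overlap between the libraries of the groups, and, per list described, up to 4 members in order of p, with up to 2 in each direction where both directions passed. Immunoglobulin and T cell receptor segments, genes named only by a clone or model number, and pseudogenes were left out of the ranking by fold change. Some genes that this rule chose are not reported here, and the counts of named gene results include them.

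The share of the most counted V gene was taken within each of the Ighv, Igkv and Iglv families in each library, and the share of each of 8 heavy-chain constant genes among all constant gene counts. Group means were compared by exact two-sided permutation tests of the libraries, adjusted over 9 and 24 tests (scipy 1.17.1). Agreement between the comparisons against YC was set beside 20 simulated data sets in which neither model differed from YC.

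The fit was tested on simulated counts drawn from the real means of the second group of each comparison, the real library sizes and the fitted dispersions, with 200 genes changed by known folds. For BIC against YC it recovered 7.46% of genes changed by 2-fold, 58.2% of those changed by 4-fold and 90.9% of those changed by 16-fold. For pBIC against YC the shares were 17.9%, 73.1% and 89.4%, and for pBIC against BIC 14.9%, 67.2% and 84.8%. It called 2, 6 and 4 of 17514 unchanged genes. A list raised in the simulation was called in each comparison. By these shares, small changes are often missed at these group sizes. The changed genes were drawn only from genes above a minimum mean count, so recovery among genes with few counts was not tested. All groups had the same dispersion for a gene, so false calls under unequal spread were not tested either. The genes were drawn independently of each other, so the simulation does not test how often correlated genes give false list calls.

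Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other low-count filters, fits without immunoglobulin genes or without genes on X and Y, thinned counts, fits with only the groups compared, a stricter threshold, a replicate block, and each library left out in turn. Settings chosen after seeing the data were counts halved and rounded, a term for Xist expression, only libraries alike in Xist expression, and pBIC 2 and 5 summed. No scaling alternative moved the median log2 fold change of all genes by 0.1 or more.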

Results

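RNA-seq counts were analysed from splenic B cells of 12 mice, sorted as B220-positive cells that carried a fluorescent reporter. B220 is a form of the surface protein CD45 found on B cells. YC mice (n = 3) were normal controls in which the Cγ1-Cre recombinase switched on a yellow reporter. Cγ1-Cre acts in B cells that transcribe the IgG1 constant gene, as germinal centre B cells do. BIC mice (n = 3) carried floxed alleles of Blimp1, encoded by Prdm1, and a transgene for a constitutively active IKK2 kinase behind a stop cassette, with the same Cre and a green reporter. IKK2, encoded by Ikbkb, is a kinase of the canonical NF-kB pathway, and Blimp1 is a transcription factor needed for plasma cell differentiation. pBIC mice (n = 6) carried floxed alleles of p53, encoded by Trp53, as well. The labels describe BIC and pBIC as mouse models of the activated B-cell type of diffuse large B-cell lymphoma (ABC-DLBCL). The design text counts the replicates as separate mice. Total gene counts ran from 33127283 in YC 3 to 47067627 in pBIC 2, and 17754 genes had enough counts to be tested.

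The groups separated on the leading principal components of the normalised counts, which held 30.4% and 20.2% of the variance. Expression is given as CPM, counts scaled to a library total of 1e6. The median SD of a gene's log2 CPM between mice was 0.267 in YC, 0.336 in BIC and 0.594 in pBIC. Without YC 1 the YC value was 0.147. All 3 YC libraries carried transcripts of Y-linked genes, with 393 to 414 CPM over Ddx3y, Eif2s3y, Kdm5d and Uty together, and at most 5.13 CPM of Xist. All 3 BIC libraries carried Xist at 1680 to 1828 CPM and almost no Y-linked transcripts. In pBIC, libraries 2, 4 and 5 carried Xist, libraries 3 and 6 carried Y-linked transcripts, and library 1 carried little of either. The BIC and YC libraries therefore differed throughout in these sex-linked transcripts as well as in genotype.

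**Figure D1:**
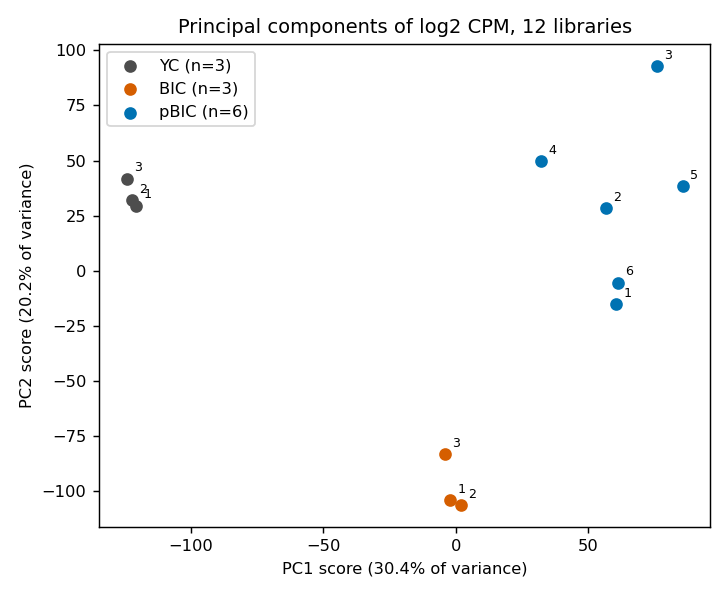
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM, with 1 point per library, coloured by group and numbered by replicate. The axes hold 30.4% and 20.2% of the variance, and the 3 groups occupy separate areas.

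The engineered genes were examined first, in every library. Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873, GRCm38) averaged 141 ± 5.30 CPM (SD, n = 3) in YC, 143 ± 68.4 CPM (n = 3) in BIC and 23.7 ± 5.27 CPM (n = 6) in pBIC. It fell in pBIC against YC (log2 fold change -2.58 ± 0.27 SE, edgeR adjusted p = 0.000191) and against BIC (-2.59 ± 0.27, edgeR adjusted p = 0.000583), and it was lower in all 6 pBIC libraries than in any of the other 6. Ikbkb (ENSMUSG00000031537.15, chromosome 8, 22659212 to 22706589) averaged 237 ± 17.5 CPM in YC, 448 ± 81.0 CPM in BIC and 488 ± 24.1 CPM in pBIC. It rose against YC in BIC (log2 fold change 0.92 ± 0.16, edgeR adjusted p = 0.00609) and in pBIC (1.04 ± 0.14, edgeR adjusted p = 0.000722), and pBIC and BIC did not differ past the threshold (0.12 ± 0.14, edgeR adjusted p = 0.562). Prdm1 (ENSMUSG00000038151.13, chromosome 10, 44437177 to 44528501) averaged 18.8 ± 1.04 CPM in YC, 26 ± 18.5 CPM in BIC and 11.6 ± 7.68 CPM in pBIC, and passed the test in no comparison (edgeR adjusted p = 0.779 for BIC against YC, 0.528 for pBIC against YC and 0.282 for pBIC against BIC). The counts sum all exons of a gene, so reads outside the floxed part of Prdm1 or Trp53 are included, and the labels do not say which exons are removed or from which sequence the transgene was made.

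**Figure D2:**
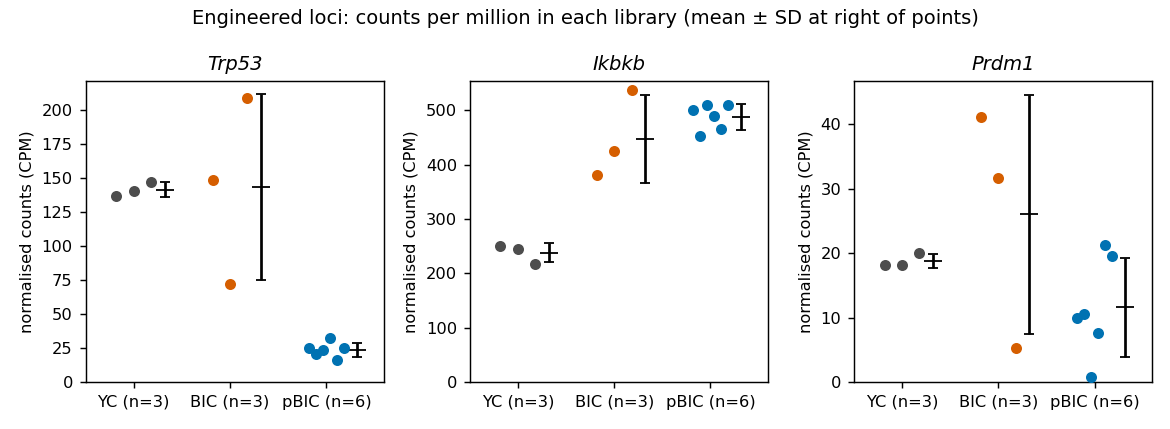
Normalised counts (CPM) of Trp53, Ikbkb and Prdm1 in each library, on linear axes that start at 0; points are libraries and the bars to their right show the mean and SD of each group. Trp53 averages 23.7 CPM in pBIC against 141 CPM in YC, Ikbkb is above the YC libraries in all BIC and pBIC libraries, and the groups overlap for Prdm1.

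The comparison of BIC with YC asks how reporter-positive B cells with active IKK2 and floxed Blimp1 differ from normal reporter-positive B cells. Of the lists called, germinal centre (10 of 23 members fell) and proliferation genes (34 of 40 fell) pointed downward in BIC, and memory and age-associated B cell genes (11 of 21 rose) upward. None of the 14 list calls held with an estimated correlation, and these lists had adjusted p = 0.0503, 0.139 and 0.269 with it. Nuggc, a nuclear GTPase of germinal centre B cells, averaged 0.254 ± 0.0828 CPM (SD, n = 3) in BIC against 224 ± 94.6 CPM (n = 3) in YC (log2 fold change -9.75 ± 1.20 SE), and Gcsam, a germinal centre signalling adaptor, averaged 0.619 ± 0.435 against 135 ± 47.7 CPM (-7.77 ± 0.87). Cd80, a co-stimulatory ligand found on memory B cells, rose by 2.66 ± 0.30 on the log2 scale. Of the 17754 genes tested, 1576 passed the threshold, 693 higher and 883 lower in BIC.

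Proliferation genes moved almost all one way in BIC against YC. Of 40 tested members 34 fell and none rose, and 39 fell when adjusted over the list alone (camera adjusted p = 1.48e-26, adjusted p = 0.139 with an estimated correlation). The mitotic cyclin Ccnb2 (-2.26 ± 0.29), the mitotic kinase Plk1 (-2.04 ± 0.27) and the centromere histone Cenpa (-1.94 ± 0.26) were among them. Of 23 germinal centre genes 10 fell and 1, Cd38, rose (16 and 2 adjusted over the list alone; camera adjusted p = 1.53e-09, adjusted p = 0.0503 with an estimated correlation). Of 22 orthologues of the human GCB classifier, genes that separate germinal-centre-type from activated-type lymphoma, 7 fell and none rose (8 adjusted over the list alone; camera adjusted p = 0.000229, adjusted p = 0.0872 with an estimated correlation). The sphingosine-phosphate receptor S1pr2 (-5.39 ± 0.78) and the transcription factor Mybl1 (-5.79 ± 1.0) were the leading members besides Gcsam. Among 26 orthologues of the ABC classifier, 4 rose and 1 fell (5 and 2 adjusted over the list alone), led by cyclin Ccnd2 (2.58 ± 0.34) and the phosphatase Ptpn1 (1.15 ± 0.20), and the list did not pass (camera adjusted p = 0.114). Of 20 naive follicular genes 4 fell, among them Ighd (-3.17 ± 0.54) and the chromatin organiser Satb1 (-3.67 ± 0.63). Adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.000101, adjusted p = 0.334 with an estimated correlation). Of the members named here, Cd38 lost its call without each of the 6 YC and BIC libraries in turn (edgeR adjusted p up to 0.129). Cd38 counts as a germinal centre gene here only because the fixed list holds it. Whether it marks these cells in mouse was not examined.

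Of 21 memory and age-associated B cell genes, 11 rose in BIC against YC and 1, the chemokine receptor Ccr6 (-5.25 ± 1.09), fell. Adjusted over the list alone 12 rose and 3 fell (camera adjusted p = 9.81e-05, adjusted p = 0.269 with an estimated correlation). Cd80 and the scaffold protein Ahnak (2.14 ± 0.26) were the leading members. Of 34 checkpoint and co-stimulation genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00458, adjusted p = 0.269 with an estimated correlation). Of 22 MHC class I genes 4 rose and none fell (7 adjusted over the list alone; camera adjusted p = 2.79e-06, adjusted p = 0.425 with an estimated correlation), among them the light chain B2m (1.22 ± 0.32). Of 31 type I interferon response genes 2 rose, Bst2 (1.97 ± 0.39) and Xaf1 (1.22 ± 0.33), also adjusted over the list alone (camera adjusted p = 0.0381, adjusted p = 0.764 with an estimated correlation). Of 22 immediate-early and heat-shock genes 1 fell, the chaperone Hspa1a (-6.44 ± 1.74), and 8 fell adjusted over the list alone (camera adjusted p = 0.000114, adjusted p = 0.459 with an estimated correlation). The NF-kB target list went both ways: of 40 members 2 rose, Ccl5 (3.95 ± 0.75) and Il15 (2.88 ± 0.77), and 5 fell (2 and 7 adjusted over the list alone), led by the growth-arrest gene Gadd45b (-4.66 ± 0.62) and the death receptor Fas (-5.21 ± 0.81). That list did not pass (camera adjusted p = 0.822), and its median log2 fold change of 0.12 and mean of -0.23 differed in sign. Of 37 p53 target genes 9 rose and 2 fell (13 and 4 adjusted over the list alone), with Zmat3 at 2.63 ± 0.40, and the list did not pass (camera adjusted p = 0.0929). The calls of Hspa1a and Il15 ended without each YC or BIC library in turn, that of B2m without each of them but BIC 3, that of Xaf1 without each but BIC 1, that of Bst2 without YC 2 or YC 3, and that of Ccr6 without BIC 2 (edgeR adjusted p up to 0.139, 0.132, 0.129, 0.151, 0.0563 and 0.0544). Hspa1a lost it without pBIC 2 too, and the interferon list lost its call without YC 2, YC 3, BIC 2 or pBIC 4.

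Markers of other blood cells were uneven between libraries, in YC as in BIC. The mean level of the neutrophil list on the log2 scale had an SD of 2.94 in YC and 2.33 in BIC, and that of the erythroid list 2.5 and 0.866, with YC 1 above the YC mean by 3.31 and 2.84. The neutrophil genes S100a8 and S100a9 stood at 163 and 271 CPM in BIC 1, 278 and 482 CPM in BIC 2, 11.3 and 18.7 CPM in BIC 3, 34.6 and 56.1 CPM in YC 1, and at most 1.36 and 2.33 CPM in YC 2 and YC 3. Of 16 neutrophil markers 1 rose, Cxcr2, and 2 rose adjusted over the list alone (camera adjusted p = 2.63e-05, adjusted p = 0.459 with an estimated correlation). Of 24 macrophage and monocyte markers 3 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 9.81e-05, adjusted p = 0.425 with an estimated correlation). Itgam, which is also in the memory and age-associated B cell list, rose by 2.78 ± 0.55, and Adgre1 changed by -2.85 ± 0.68. Of 14 NK cell markers 2 rose, Ccl5 and Nkg7 (3 adjusted over the list alone; camera adjusted p = 0.0182, adjusted p = 0.425 with an estimated correlation), and of 25 T cell markers 1 rose, Cd3g (4.55 ± 0.89), also adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.459 with an estimated correlation). None of 11 megakaryocyte markers passed on its own, adjusted over the list alone or not (camera adjusted p = 0.0481, adjusted p = 0.459 with an estimated correlation). The calls of Adgre1 ended without each YC or BIC library in turn, those of Nkg7 without each but BIC 3, those of Cxcr2 without YC 2, YC 3, BIC 1, BIC 2 or pBIC 2, those of Itgam without YC 2 or YC 3 and those of Cd3g without YC 1 or YC 3 (edgeR adjusted p up to 0.0993, 0.121, 0.154, 0.0569 and 0.0524). The T cell list lost its call without YC 1 and the megakaryocyte list without any library but YC 1, BIC 1 and pBIC 3. The lists that did not pass were marginal zone genes (2 of 15 rose, Cd9 at 3.52 ± 0.34 and Fcrl5 at 3.59 ± 0.67), B cell identity (1 of 22 rose), plasma cell (1 of 23 rose), B cell receptor signalling (1 of 28 fell), MHC class II (1 rose and 1 fell of 16), unfolded protein response (1 of 24 rose), dendritic cell (2 rose and 1 fell of 12) and plasmacytoid dendritic cell markers (3 rose and 1 fell of 13). In the MYC target, oxidative phosphorylation, glycolysis, JAK-STAT3, erythroid and stromal lists no member passed.

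Among the genes with the highest fold changes in BIC were Erich2 (8.22 ± 2.23), the extracellular matrix gene Fras1 (7.78 ± 1.96, 413 ± 176 against 1.89 ± 0.771 CPM), the receptor kinase gene Ephb4 (7.36 ± 1.32), Trim40 (7.31 ± 1.57) and the nuclear receptor gene Nr5a2, which had 713 counts in BIC and 2 in YC, a ratio of 374 after scaling to total counts (95% exact interval 66.8 to 14841 on counts halved, because mates were counted separately). The lowest were Y-linked Ddx3y (-10.56 ± 2.86), Nuggc, the actin nucleator Cobl (-8.81 ± 1.46), the calcium channel gene Ryr2 (-8.20 ± 2.04), Pxdc1 (-7.88 ± 1.27) and Gcsam. The groups did not overlap for 1574 of the 1576 called genes, and for 45.2% of all tested genes, where chance gives 10%. The count of 1576 was 734 without YC 1, 563 without YC 2, 569 without YC 3, 603 without BIC 1, 619 without BIC 2, 3032 with DESeq2 and 4602 with only these 2 groups in the fit. The share of calls that were higher in BIC was 44%, and over 50% with only these 2 groups (50.6%), with a term for Xist expression (54.8%) and without BIC 2 (51.4%). The calls of Erich2, Fras1, Ddx3y and Ryr2 ended without each of the 6 YC and BIC libraries in turn, and that of Trim40 without each YC library (edgeR adjusted p up to 0.148, 0.117, 0.137, 0.1 and 0.0747 for Erich2, Fras1, Ddx3y, Ryr2 and Trim40). With fry 8 lists were called, 6 of them among the 14. The calls that ended were those of MHC class I (fry adjusted p = 0.0625), interferon (0.534), immediate-early and heat-shock (0.126), T cell (0.145), NK cell (0.0734), macrophage (0.0856), neutrophil (0.136) and megakaryocyte genes (0.142). The other 2 were the p53 target and plasmacytoid dendritic cell lists. With a term for Xist expression, chosen after seeing the data, 5 lists were called. The calls of the naive follicular (camera adjusted p = 0.0824), checkpoint (0.374), interferon (0.0964), T cell (0.861), NK cell (0.303), macrophage (0.0964), neutrophil (0.258) and megakaryocyte lists (0.191) ended, and the immediate-early and heat-shock list pointed upward (camera adjusted p = 0.819; 4.81e-06 to 0.819 over all alternatives).

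The comparison of pBIC with YC asks how the same genotype with floxed p53 differs from normal cells. Of the lists called, MYC target and ribosome biogenesis (26 of 30 members rose) and oxidative phosphorylation genes (21 of 28 rose) pointed upward in pBIC, and germinal centre (14 of 23 fell), MHC class II (12 of 16 fell) and B cell receptor signalling genes (11 of 28 fell) downward. Of the 12 list calls only that of germinal centre genes held with an estimated correlation, and the other lists named had adjusted p = 0.203, 0.289, 0.178 and 0.126 with it. The ribosome assembly factors Mrto4 and Nop2 rose by 1.62 ± 0.19 and 1.70 ± 0.20 on the log2 scale (SE). Gcsam averaged 0.127 ± 0.121 CPM (SD, n = 6) against 135 ± 47.7 CPM (n = 3) in YC (-10.0 ± 0.70), and H2-Ab1, an MHC class II chain, changed by -1.49 ± 0.21. Of the 17754 genes, 3914 passed, 2103 higher and 1811 lower in pBIC.

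Of 30 MYC target and ribosome biogenesis genes, 26 rose in pBIC against YC and none fell (27 adjusted over the list alone; camera adjusted p = 1.8e-16, adjusted p = 0.203 with an estimated correlation). Of 28 oxidative phosphorylation genes 21 rose and none fell (25 adjusted over the list alone; camera adjusted p = 2.03e-10, adjusted p = 0.289 with an estimated correlation). The ATP synthase subunit Atp5b was at 1.16 ± 0.21 and the complex subunit Ndufa4 at 1.08 ± 0.16 on the log2 scale. Of 18 glycolysis genes 8 rose and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00472, adjusted p = 0.479 with an estimated correlation). The kinase Pdk1 was at 1.75 ± 0.30 and Tpi1 at 1.43 ± 0.27 on the log2 scale. Of 40 proliferation genes only Tyms, the thymidylate synthase, passed and rose (1.18 ± 0.20), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.374).

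Of 23 germinal centre genes 14 fell and none rose, also adjusted over the list alone. The list passed with the preset and with an estimated correlation (camera adjusted p = 3.18e-11, adjusted p = 0.0288 with an estimated correlation). S1pr2 (-5.36 ± 0.58), Nuggc (-8.28 ± 0.81) and Basp1 (-6.12 ± 0.81) were leading members. Of 22 GCB classifier orthologues 10 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 6.58e-05, adjusted p = 0.0553 with an estimated correlation). The kinase Itpkb was at -2.22 ± 0.24 and the transcription factor Myb at 1.93 ± 0.43 on the log2 scale. Of 20 naive follicular genes 11 fell and none rose (15 adjusted over the list alone; camera adjusted p = 2.36e-08, adjusted p = 0.126 with an estimated correlation), led by Satb1 (-5.16 ± 0.51) and Ighd (-4.38 ± 0.43). Of 22 B cell identity genes 12 fell and none rose (16 adjusted over the list alone; camera adjusted p = 8.05e-08, adjusted p = 0.15 with an estimated correlation), among them Ptprc, which encodes CD45 (-1.75 ± 0.18), and the inhibitory receptor Cd22 (-1.37 ± 0.23). Of 28 B cell receptor signalling genes 11 fell and none rose (15 adjusted over the list alone; camera adjusted p = 8.05e-08, adjusted p = 0.126 with an estimated correlation), including the phospholipase Plcg2 (-1.03 ± 0.18) and the adaptor Pik3ap1 (-1.51 ± 0.28). Of 16 MHC class II genes 12 fell and none rose (13 adjusted over the list alone; camera adjusted p = 2.31e-07, adjusted p = 0.178 with an estimated correlation). The peptide-loading chain H2-DMb1 was at -1.74 ± 0.19 on the log2 scale.

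Of 22 JAK-STAT3 genes 6 fell, among them the kinases Jak1 (-1.45 ± 0.21) and Jak2 (-1.21 ± 0.24), and 1, the cytokine Il10 (4.07 ± 1.20), rose, also adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.479 with an estimated correlation). Of 40 NF-kB targets 7 fell and 2 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.0439, adjusted p = 0.811 with an estimated correlation). The call ended with fry (fry adjusted p = 0.141) and in both settings that took account of Xist (camera adjusted p = 0.338 and 0.283). The mean level of the list on the log2 scale was above that of YC in pBIC 1 (by 0.134) and pBIC 6 (0.415) and below it in the others (-1.39 to -0.625). Slamf1 was at -5.43 ± 0.68 and Fas at -3.54 ± 0.57 on the log2 scale. Of 22 immediate-early and heat-shock genes 6 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.000559, adjusted p = 0.711 with an estimated correlation), with Nr4a1 at -3.19 ± 0.72. That call ended with fry and in both settings that took account of Xist. The mean level of the list was close to YC in pBIC 1 (-0.0731) and at -0.681 in pBIC 6, against -2.76 to -2.13 in the others. The remaining lists did not pass. They were memory and age-associated (7 rose and 4 fell of 21), marginal zone (2 and 4 of 15), checkpoint (1 and 4 of 34), MHC class I (4 and 1 of 22), p53 target (4 and 5 of 37), plasma cell (1 and 4 of 23), ABC classifier (2 and 4 of 26), interferon (2 and 1 of 31) and unfolded protein response genes (3 and 2 of 24). Among markers of other cells, T cell (0 and 1 of 25), NK cell (2 and 2 of 14), macrophage (0 and 3 of 24), dendritic (1 and 3 of 12), plasmacytoid dendritic (3 and 3 of 13) and stromal markers (1 and 0 of 11) did not pass either, and no neutrophil, erythroid or megakaryocyte marker passed. Of these lists, fry called the p53 target and dendritic lists, both downward (fry adjusted p = 0.0294 and 0.00346). The plasma cell gene Sdc1 changed by -2.96 ± 0.68 and Jchain by -5.63 ± 1.37.

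Among the highest fold changes in pBIC were those of Sat2, Nr5a2, the transcription factor gene Ebf3 (8.69 ± 2.26), Mpp3 (8.28 ± 1.69) and Spats2 (7.91 ± 2.18). Sat2, which lies 30.2 kb from Trp53 on chromosome 11 (69622024 to 69623870), had 2862 counts in pBIC and 2 in YC, a ratio of 717 after scaling to total counts (95% exact interval 129 to 28346 on counts halved), and Nr5a2 had 2507 and 2, a ratio of 628 (113 to 24843). The lowest were Gcsam, Cobl (-8.35 ± 1.03), Nuggc, the transporter genes Slc22a15 (-6.85 ± 0.55) and Slc41a2 (-6.82 ± 0.48), and Ccr6 (-6.65 ± 0.86). The groups did not overlap for 3519 of the 3914 called genes and for 26.1% of all tested genes, where chance gives 2.38%. The share of calls that were higher in pBIC was 53.7%, and under 50% with limma-voom (43.1%), without a low-count filter (48.8%), at an adjusted p under 0.01 (48.1%) and without 1 YC library (45.6% to 49.4%). The count was 2223 without YC 1, 1904 without YC 2 and 2328 without YC 3, and the calls of Ebf3 and Spats2 ended without each of these libraries in turn (edgeR adjusted p up to 0.0731 and 0.096), as did that of Il10 (up to 0.111). The JAK-STAT3 list lost its call without YC 1, and the NF-kB list without YC 1, pBIC 3 or pBIC 4.

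**Figure D3:**
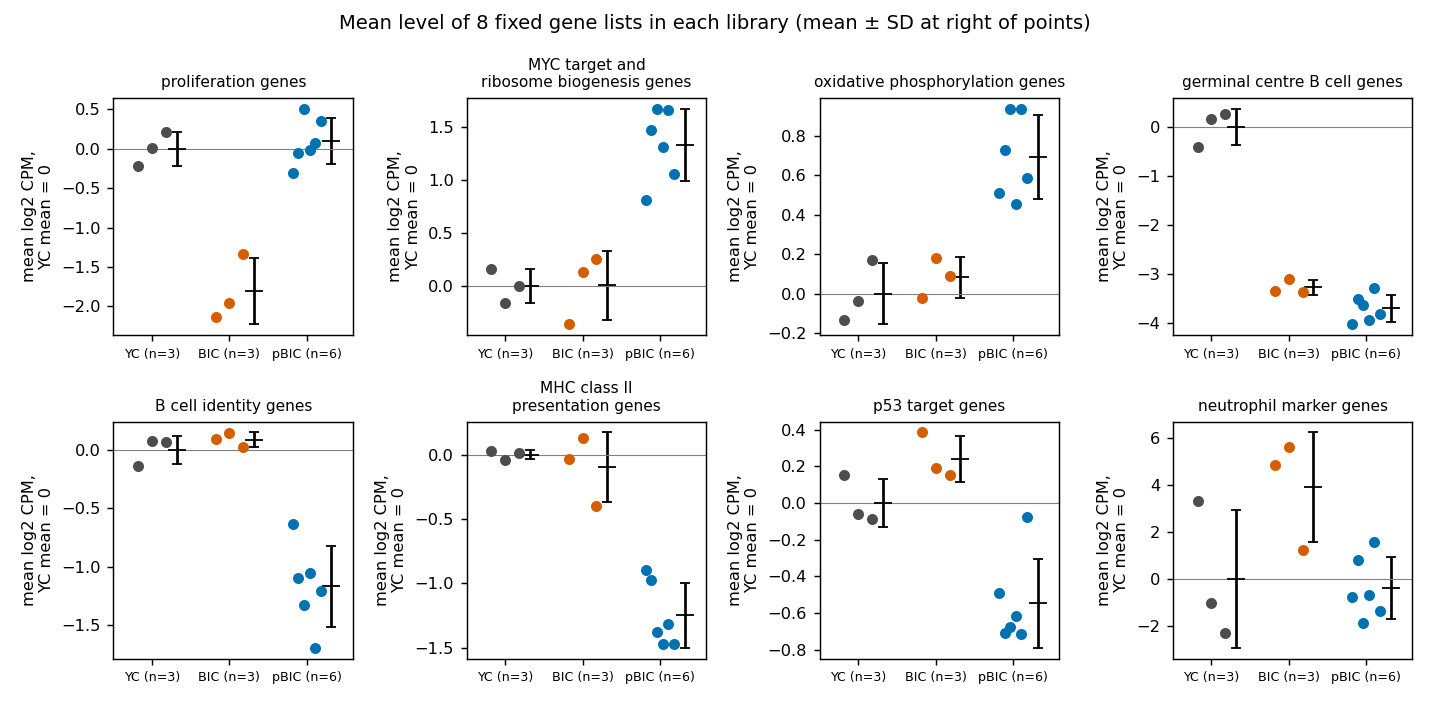
Mean log2 CPM of the members of 8 fixed gene lists in each library, shifted so that the YC mean is 0; points are libraries and the bars to their right show the mean and SD of each group. Proliferation genes average -1.81 in BIC and 0.09 in pBIC, MYC target and ribosome biogenesis genes average 0.01 and 1.33, and neutrophil markers spread from 1.25 to 5.6 across BIC.

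The comparison of pBIC with BIC asks what differs between the tumour models with and without floxed p53. Of the lists called, proliferation (38 of 40 members rose), MYC target and ribosome biogenesis (29 of 30) and oxidative phosphorylation genes (16 of 28) pointed upward in pBIC, and B cell identity (14 of 22 fell), MHC class II (12 of 16), checkpoint and co-stimulation (9 of 34) and p53 target genes (12 of 37) downward. None of the 21 list calls held with an estimated correlation (adjusted p = 0.123 to 0.613 with an estimated correlation). The transporter gene Slc16a1 averaged 129 ± 64.3 CPM (SD, n = 6) in pBIC against 3.01 ± 1.22 CPM (n = 3) in BIC (log2 fold change 5.42 ± 0.66 SE), and the amino acid transaminase Bcat1 72.2 ± 44.1 against 1.24 ± 0.840 CPM (5.85 ± 0.86). The p53 target gene Phlda3 averaged 0.153 ± 0.0989 against 22.7 ± 12.3 CPM (-7.18 ± 0.90), and the ligands Tnfsf8 and Tnfsf4 (OX40 ligand) changed by -7.85 ± 0.82 and -4.93 ± 0.83. Of the 17754 genes, 3496 passed, 1937 higher and 1559 lower in pBIC.

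Of 40 proliferation genes 38 rose in pBIC against BIC and none fell (40 adjusted over the list alone; camera adjusted p = 1.24e-26, adjusted p = 0.123 with an estimated correlation). Tyms was at 2.37 ± 0.22 and the checkpoint kinase Ttk at 2.62 ± 0.27 on the log2 scale. Of 30 MYC target and ribosome biogenesis genes 29 rose and none fell (30 adjusted over the list alone; camera adjusted p = 1.84e-18, adjusted p = 0.147 with an estimated correlation). Nucleophosmin (Npm1) was at 1.65 ± 0.27 and Cdk4 at 1.26 ± 0.20 on the log2 scale. Of 28 oxidative phosphorylation genes 16 rose and none fell (24 adjusted over the list alone; camera adjusted p = 2.47e-09, adjusted p = 0.186 with an estimated correlation), and of 18 glycolysis genes 8 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.00292, adjusted p = 0.283 with an estimated correlation). Ldha was at 1.85 ± 0.39 on the log2 scale. Of 37 p53 target genes 12 fell and 1, Ckap2, rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.00103, adjusted p = 0.123 with an estimated correlation). Cyclin Ccng1 changed by -2.07 ± 0.24.

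Of 22 B cell identity genes 14 fell in pBIC against BIC and none rose (15 adjusted over the list alone; camera adjusted p = 1.62e-09, adjusted p = 0.123 with an estimated correlation), among them the kinase Syk (-1.67 ± 0.20) and Ptprc (-1.19 ± 0.18). Of 16 MHC class II genes 12 fell and none rose (13 adjusted over the list alone; camera adjusted p = 1.45e-08, adjusted p = 0.123 with an estimated correlation). H2-Aa was at -1.55 ± 0.21 on the log2 scale. Of 28 B cell receptor signalling genes 9 fell and none rose (10 adjusted over the list alone; camera adjusted p = 2.7e-06, adjusted p = 0.123 with an estimated correlation), including the kinase Lyn (-1.30 ± 0.18). Of 34 checkpoint and co-stimulation genes 9 fell and none rose (14 adjusted over the list alone; camera adjusted p = 4.76e-06, adjusted p = 0.123 with an estimated correlation). Cd80 was at -1.47 ± 0.24 and Cd200 at -2.70 ± 0.49 on the log2 scale. Of 21 memory and age-associated genes 7 fell and none rose (9 adjusted over the list alone; camera adjusted p = 1.04e-05, adjusted p = 0.123 with an estimated correlation), led by Ahnak (-1.62 ± 0.21). Of 15 marginal zone genes 5 fell (7 adjusted over the list alone; camera adjusted p = 0.00105, adjusted p = 0.186 with an estimated correlation). Dtx1 was at -2.35 ± 0.27 on the log2 scale. Of 26 ABC classifier orthologues 6 fell, also adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.186 with an estimated correlation). Of 22 JAK-STAT3 genes 5 fell (6 adjusted over the list alone; camera adjusted p = 0.000226, adjusted p = 0.173 with an estimated correlation). Jak3 was at -1.18 ± 0.22 on the log2 scale. Of 22 MHC class I genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.00493, adjusted p = 0.468 with an estimated correlation), and of 20 naive follicular genes 3 fell (1 adjusted over the list alone; camera adjusted p = 0.00598, adjusted p = 0.283 with an estimated correlation). H2-M3 was at -1.57 ± 0.26 and Il4ra at -1.82 ± 0.30 on the log2 scale. Of 40 NF-kB targets 4 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.0416, adjusted p = 0.613 with an estimated correlation), and the median of -0.24 and mean of 0.07 differed in sign.

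Of 16 neutrophil markers 14 fell in pBIC against BIC (15 adjusted over the list alone; camera adjusted p = 9.57e-07, adjusted p = 0.283 with an estimated correlation). Csf3r was at -3.95 ± 0.70 and Ly6g at -4.84 ± 1.08 on the log2 scale. Of 24 macrophage markers 3 fell, also adjusted over the list alone (camera adjusted p = 4.86e-05, adjusted p = 0.283 with an estimated correlation). Itgam was at -2.29 ± 0.43 and Spic at -2.58 ± 0.49 on the log2 scale. Of 25 T cell markers 3 fell (1 adjusted over the list alone; camera adjusted p = 1.11e-05, adjusted p = 0.186 with an estimated correlation). Cd3g was at -3.92 ± 0.66 on the log2 scale. Of 14 NK cell markers 3 fell, also adjusted over the list alone (camera adjusted p = 0.000783, adjusted p = 0.186 with an estimated correlation), and of 11 megakaryocyte markers 1 fell, Ppbp (-4.18 ± 0.86), also adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.326 with an estimated correlation). The lists that did not pass were germinal centre (1 rose and 5 fell of 23), GCB classifier (2 and 3 of 22), plasma cell (1 and 3 of 23), interferon (0 and 1 of 31), unfolded protein response (3 and 2 of 24, with asparagine synthetase, Asns, at 3.57 ± 0.70), immediate-early and heat-shock (2 and 0 of 22), dendritic (1 and 2 of 12), plasmacytoid dendritic (0 and 1 of 13), erythroid (1 and 0 of 15) and stromal (0 and 0 of 11). Of these lists, fry called the dendritic and plasmacytoid dendritic lists, both downward (fry adjusted p = 0.00091 and 0.00547).

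The highest fold changes in pBIC against BIC were those of Ddx3y (8.05 ± 2.59), Nes (6.30 ± 1.98), Tead1 (6.15 ± 2.0), Bcat1, Slc16a1 and Nt5dc2 (4.89 ± 1.0), and among the lowest were those of the X-linked gene Xlr3b (-8.28 ± 1.03), Tnfsf8, Phlda3, Tnfsf4 and Dglucy (-4.89 ± 0.42). The share of calls that were higher in pBIC was 55.4%, and under 50% with limma-voom (47.5%) and without a low-count filter (49.6%). The groups did not overlap for 2913 of the 3496 called genes and for 21.6% of all tested genes, where chance gives 2.38%. The count was 1422 without BIC 1, 1673 without BIC 2 and 2315 without BIC 3. The calls of Nes, Ddx3y and Tead1 ended without each YC or BIC library in turn, and those of Ddx3y and Tead1 also without pBIC 3 or pBIC 6 (edgeR adjusted p up to 0.149, 0.153 and 0.152). The MHC class I and megakaryocyte lists lost their calls without BIC 2, and the NF-kB list without BIC 2, pBIC 3 or pBIC 4. The calls of the NF-kB and MHC class I lists also ended with fry (fry adjusted p = 0.255 and 0.0921).

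Both tumour models were set against the same 3 YC libraries, so their fold changes were also compared with each other. Across genes, which are not independent replicates, the log2 fold changes of BIC and pBIC against YC correlated with Pearson's r = 0.642. Unchanged groups simulated against the same controls gave 0.608 on average (0.591 to 0.622 in 20 draws). Spearman's rho was 0.524, and 0.546 on average in the simulation. The covariance was 1.72 against 0.385 simulated, a difference of 1.33. The simulation gave all groups the same dispersion for a gene, while the median SD between mice was 0.267 in YC and 0.594 in pBIC. It may therefore overstate how much correlation and covariance the shared controls give. Of the called genes 343 were higher in both models and 418 lower in both, where independent lists would share 82.1 and 90.1, and 19 genes were called in opposite directions. The 3 controls cannot be split into parts of at least 2 libraries, and part of the excess may come from sharing them. The number of shared calls, 761, was 357 without YC 1, 274 without YC 2, 290 without YC 3, 363 without BIC 1 and 352 without BIC 2.

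Immunoglobulin V genes give a view of whether few B cell clones dominate a library, because each clone uses 1 rearranged heavy and light chain. The share of 1 V gene does not count clones, since separate clones can use the same V gene. The most counted Ighv gene took 7.78% ± 1.05 (SD, n = 3) of Ighv counts in YC, 46.0% ± 19.6 (n = 3) in BIC and 69.6% ± 25.7 (n = 6) in pBIC. The most counted Igkv gene took 8.5% ± 2.62, 53.8% ± 17.4 and 84.6% ± 14.9. Every tumour library was above every YC library for both. Exact two-sided permutation tests gave p = 0.10 for BIC against YC in both families, the smallest that 3 against 3 mice can give (adjusted p = 0.18 over 9 tests). The same exact permutation tests gave p = 0.0238 for pBIC against YC in both, the smallest that 6 against 3 can give (adjusted p = 0.107), so no family passed after adjustment. Between pBIC and BIC the exact permutation p was 0.0476 for Igkv and 0.238 for Ighv (adjusted p = 0.143 and 0.306). For Iglv, with 62 to 10692 counts a library, the most counted of 3 genes took 61.7% ± 9.12, 75.4% ± 8.69 and 69.2% ± 13.5, and the exact permutation p were 0.20, 0.429 and 0.50 for BIC against YC, pBIC against YC and pBIC against BIC (adjusted p = 0.30, 0.482 and 0.50).

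**Figure D4:**
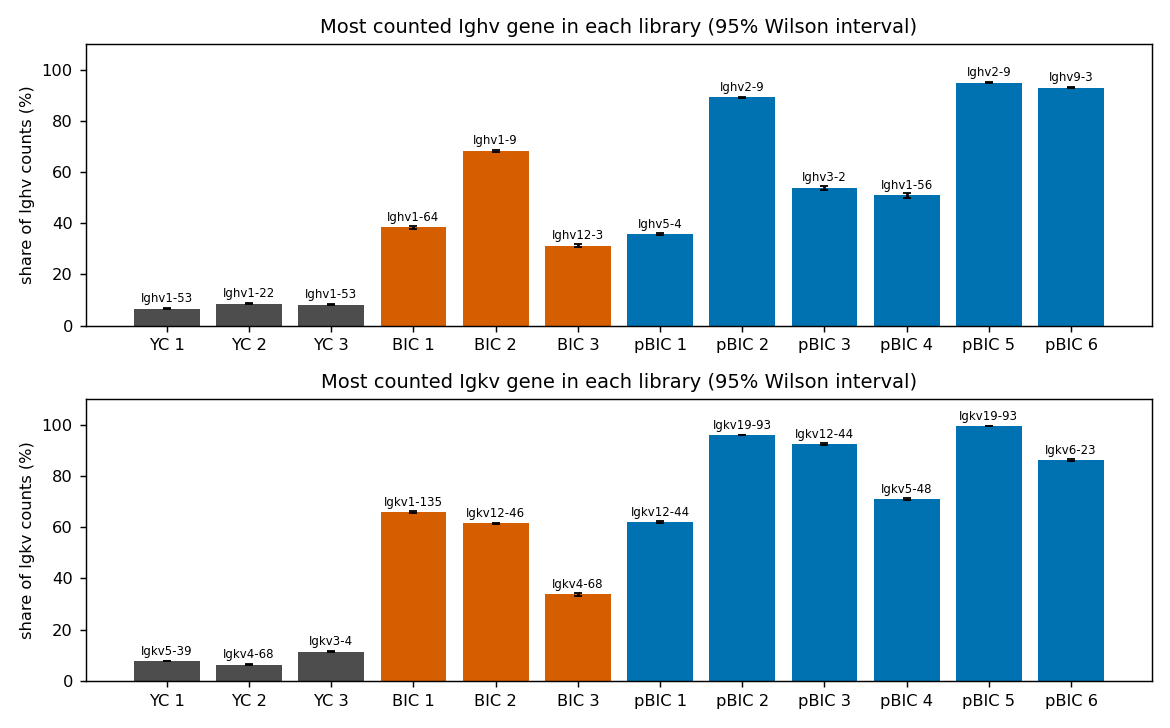
Share of the most counted Ighv gene (top) and Igkv gene (bottom) among all counts of its family in each library, with the name of that gene above each bar and its 95% Wilson interval, which covers counting error only. The shares lie between 6.35% and 11.4% in the YC libraries and between 31.3% and 99.4% in the BIC and pBIC libraries.

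The dominant V genes differed between most tumours. Ighv2-9 (chromosome 12, 113879096 to 113879541) and Igkv19-93 (chromosome 6, 68736297 to 68736780) dominated both pBIC 2, with 89.1% (95% Wilson interval 88.9 to 89.4) and 96.1% (95.9 to 96.2), and pBIC 5, with 94.9% (94.7 to 95) and 99.4% (99.3 to 99.5). In YC these genes took 1.99% and 2.65% of their families' counts. pBIC 1 and pBIC 3 shared Igkv12-44 as the dominant light chain gene but differed in the heavy chain gene. Near-identical V genes can share reads, so the share of a single V gene is uncertain to that extent.

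Ighm led among the heavy-chain constant genes in every YC library, while the leading gene and its share varied between tumours. Ighm took 70.7% to 73.2% of constant gene counts in YC. Ighg3 led in BIC 1 and BIC 2, with 69.0% and 58.0%, and Ighm in BIC 3, with 92.4%. Among pBIC libraries, Ighg2b took 85.2% in pBIC 3 and Ighg1 68.6% in pBIC 4, and Ighm took over 93% in the other 4. The share of Ighd averaged 4.72% ± 0.179 in YC, 0.857% ± 0.399 in BIC and 0.578% ± 0.332 in pBIC (exact permutation p = 0.10 and 0.0238 against YC, the smallest possible; adjusted p = 0.20 and 0.143). No constant gene passed in any comparison after adjustment over 24 tests. Of the immunoglobulin and T cell receptor gene segments that passed in the edgeR test, 82 were lower and 1 higher in BIC against YC, and all 174 were lower in pBIC against YC.

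**Figure D5:**
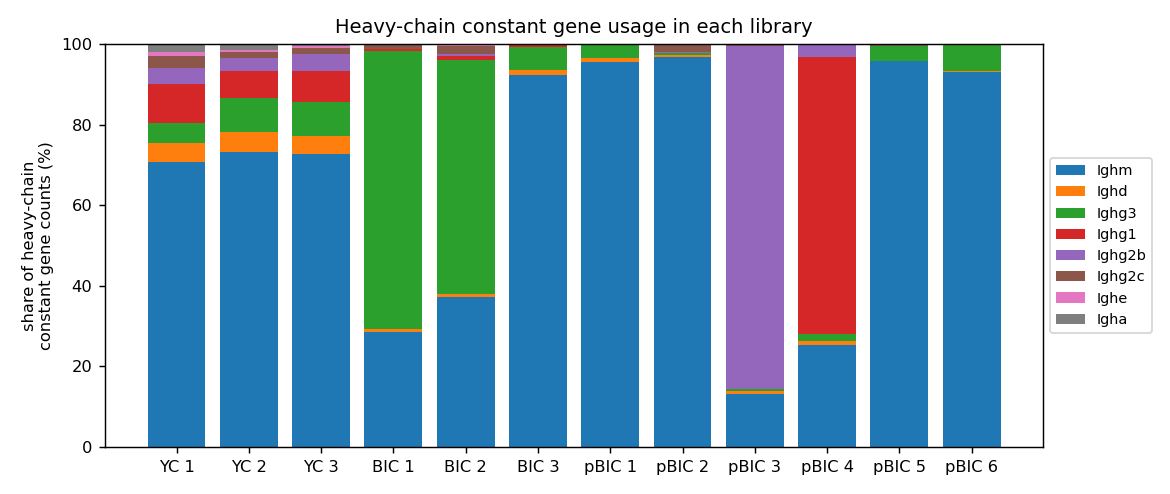
Share of each heavy-chain constant gene among all heavy-chain constant gene counts in each library, as stacked bars that add up to 100%. Ighm takes 70.7% to 73.2% in YC, Ighg3 leads in BIC 1 and 2, Ighg2b in pBIC 3, Ighg1 in pBIC 4 and Ighm in the remaining tumour libraries.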

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

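The tests of neutrophil and T cell RNA, of sex and of shared V genes were chosen only after the results they bear on were seen, and the counts over other splits of the libraries were planned.

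Genes that divide the models were those called in opposite directions against YC in BIC and pBIC with a difference that itself passed between pBIC and BIC. There were 19, of which 12 were lower in BIC and higher in pBIC. They include Orc1 (-1.65 in BIC and 1.01 in pBIC, log2 against YC), Cks1b (-1.28 and 1.01), Tyms (-1.19 and 1.18), Cenpw (-1.29 and 1.29) and Mnd1 (-1.41 and 1.51), and the transaminase Bcat1 (-3.33 and 2.52). The other 7, higher in BIC and lower in pBIC, include Kif13a (2.6 and -1.99), Dglucy (3.63 and -1.27), the chemokine receptor Ccr1 (2.37 and -1.59) and the transcription factor Zbtb7b (0.98 and -1.07).

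Single pBIC libraries lay far from the other 5 for 14 of 213 values examined, where chance alone gives about 1 in 20. The value after each name is the gap to the nearest library divided by the range of all 6, on the log2(CPM + 0.1) scale for genes. pBIC 3 was lowest for Prdm1 (0.684; 0.718 CPM against 7.52 to 21.3), Jak3 (0.834; 54.6 against 102 to 116 CPM), H2-M3 (0.629), Csf3r (0.650) and the ABC classifier list (0.634), and highest for Sparc (0.758; 5.91 against at most 1.16 CPM) and for the Ighg2b share (0.964; 85.2% against at most 3.07%). pBIC 6 was lowest for Mpp3 (0.722; 0.378 against at least 10.6 CPM) and H2-Eb2 (0.691) and highest for the p53 target list (0.654). pBIC 1 was lowest for Sdc1 (0.709) and pBIC 4 for Tyms (0.694). pBIC 4 was highest for the Ighg1 share (0.999; 68.6% against at most 0.128%) and pBIC 2 for the Ighg2c share (0.874; 1.82% against at most 0.274%).

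Neutrophil markers were higher in BIC 1 and 2, and Cd3g was higher in BIC, although the sort selected B220-positive GFP-positive cells. Expression of the 16 neutrophil markers by BIC tumour cells stays open, because their lower level in BIC 3, 0.0546 of the mean of BIC 1 and 2 (median over the genes), is the pattern itself and separate tumours need not be alike. RNA from neutrophils in the sorted cells also remains a candidate explanation. The marker profile of YC 1 correlated with that of BIC 1 and 2 across genes (r = 0.813). That correlation does not tell the explanations apart, because the markers differ widely in level and no profile from another source was set beside it. S100a9 reached 482 CPM in BIC 2, and none of the 16 markers is in another list. In YC 7 of the 16 markers are above 5 CPM on average. YC 1 stood apart there, with a mean log2 CPM of 3.28 for the list, against -1.05 in YC 2 and -2.31 in YC 3. For Cd3g, which encodes a chain of the CD3 complex of T cells, the ratio to Cd3e plus Cd3d was 9.39 in BIC 1, 19.2 in BIC 2 and 1.28 in BIC 3, against at most 1.58 in YC, so that in 2 of 3 BIC libraries RNA from T cells does not account for it, while for BIC 3 that stays open.

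The YC mice carried Y-linked transcripts and the BIC mice carried Xist, so sex, as read from these transcripts, differed with genotype in that comparison. The pBIC libraries, some with Xist and some without, allow a term for it. Its size comes from these libraries alone, because Xist was low in every YC library and high in every BIC library. If sex caused the autosomal differences, and acted there as among the pBIC libraries, the term would remove them. Instead the log2 fold changes of the 1531 called autosomal genes with the term were 1.01 times those without it (median, quartiles 0.821 to 1.20). All kept their direction. These values argue against a sex effect like that among the pBIC libraries as the cause for these genes as a set. A sex effect of another kind between YC and BIC cannot be told apart from genotype. The gene lists were less stable than these genes. With the term several list calls of BIC against YC ended, among them those of the T cell (camera adjusted p = 0.861) and checkpoint lists (0.374). The germinal centre and proliferation lists were not among those that ended. With the term the median SE of the 1531 genes rose from 0.44 to 0.56, and 676 of them were still called. Other genes became called with it, so a larger SE alone does not describe the change in calls. Sex may still contribute to single genes, and genotype remains an open explanation that was tested apart from sex only through this term.

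pBIC 2 and pBIC 5 shared both dominant V genes, alone among 36 pairs of tumour libraries. That count and the probabilities below take only the most counted gene of each family. With the second gene included, BIC 2 and BIC 3 shared Ighv12-3 (22.5% and 31.3%) and Igkv4-91 (22.8% and 27.9%). Igkv19-93 also took 32.9% of Igkv counts in pBIC 1, as its second gene. A single library deposited under both names is excluded by a chi-square of 130 per gene between them. Separate clones that used the same V genes by chance stay open: the probability that any pair would share both is 0.0218 at the usage of the YC libraries, but V genes may be favoured in tumours, and the bound from how often the other 35 pairs shared each gene is 0.317. Cells of 1 clone in both libraries, which would leave fewer than 6 independent pBIC replicates, also remain a candidate explanation, since outside the immunoglobulin genes they were also the most alike pair of pBIC libraries (r = 0.979 across genes, next pair 0.968). No biological explanation from the design was tested, because it gives no group that separates these libraries from the other pBIC libraries.

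Other splits of the same libraries were refitted for each comparison. For pBIC against YC 1 of 84 splits, the real one, reached its 3914 genes, and the highest other split gave 907. For pBIC against BIC 1 of 84 splits, the real one, reached 3496, with 1137 as the highest other. In both, chance is unlikely but not excluded, since 1 of 84 is the lowest share that these splits can give. The splits also take the pBIC libraries as independent, which cells of 1 clone in more than 1 of them would break. For BIC against YC the 10 splits are too few for a share under 0.05; 1 split, the real one, reached 1576 genes, and the highest other gave 0. For the lists, 42 of 84 splits gave at least the 12 calls of pBIC against YC (highest other 22) and 10 of 84 at least the 21 of pBIC against BIC (highest other 22), so chance is not excluded for either count. For BIC against YC 4 of the 10 splits gave at least 14 lists (highest other 18), and 10 splits are too few for a share under 0.05.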

How the results depend on the processing

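The settings for Xist, halved counts and pBIC 2 and 5 summed were chosen after seeing the data; the others were planned. At an adjusted p under 0.01 the counts of called genes were 425 for BIC against YC, 1766 for pBIC against YC and 1313 for pBIC against BIC. Leaving out 1 library at a time gave 563 to 1867, 1904 to 4376 and 1422 to 4134, with fewer mice in the fit. BIC against YC gave 3032 calls with DESeq2, and the cause was not tested. It gave 4602 with only those groups in the fit, where the spread of the pBIC libraries no longer enters. With a term for Xist, 1311 genes were called for BIC against YC, 691 of them among the 1576. With libraries alike in Xist expression 2953 and 3501 genes were called for pBIC against YC and pBIC against BIC, 2337 and 2364 of them shared. Halved counts gave 1694, 4044 and 3681 calls, and pBIC 2 and 5 summed 1673, 3687 and 3147. Counts of lists fell to 0, 1 and 0 with an estimated correlation, and for BIC against YC to 8 with fry and 5 with the Xist term; the cause was not tested. The immediate-early and heat-shock list turned upward for BIC against YC with the Xist term (camera adjusted p = 0.819; range over its alternatives 4.81e-06 to 0.819), and the cause was not tested. The correlation of BIC and pBIC fold changes ranged from 0.577 to 0.677 without 1 library and was 0.724 with the Xist term, and the shared calls from 274 to 890; the cause was not tested. The median SD between mice fell to 0.202 in YC, 0.265 in BIC and 0.493 in pBIC with the CPM filter, which tests fewer low genes. Without 1 library it ranged from 0.147 to 0.272, 0.246 to 0.295 and 0.555 to 0.595.

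Among the 272 named gene results, no call changed direction. Of 3516 values under planned settings that keep all libraries 3350 stayed on the same side of the threshold and 166 were weaker; of 3264 values without 1 library 2813 stayed and 451 were weaker; of 1011 values under the settings added later 912 stayed and 99 were weaker. For the lists 572 of 648 values under planned settings that keep all libraries stayed, 67 were weaker, 46 of them with an estimated correlation, and 9 stronger, and 1078 of 1116 values without 1 library stayed, 23 were weaker and 15 stronger; of 341 under the settings added later 314 stayed, 20 were weaker, 6 stronger and 1 reversed. All 192 values of constant gene shares without 1 library, the 24 with the other denominator and all values of V gene shares stayed, in tests of which none passed. The CPM filter left out 1 list and some named genes, for which it gives no value. The replicate numbers showed no clear pairing of the mice. Deviations of same-numbered libraries correlated at -0.0948 to 0.155, and 4 of 9 libraries matched best with their own number. With so few libraries a pairing is not excluded. A replicate block gave 1725, 3144 and 2424 calls. Depth limits low levels, since 3 counts are 0.0637 to 0.0906 CPM. Thinning to the smallest library gave 1578, 3973 and 3472 called genes and ended 4 calls among 270 named gene results.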

Other observations

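The genes and tests in this part were chosen after their values were seen. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 regulator p19Arf, averaged 2.84 ± 1.06 CPM (SD, n = 3) in YC, 23.3 ± 15.6 CPM (n = 3) in BIC and 209 ± 115 CPM (n = 6) in pBIC. It was higher in pBIC than in YC (log2 fold change 6.20 ± 1.0 SE, edgeR adjusted p = 0.00165) and than in BIC (3.17 ± 0.84, edgeR adjusted p = 0.0218), and BIC against YC did not pass (3.03 ± 0.89, edgeR adjusted p = 0.0555). In pBIC 6 it stood at 11.7 CPM against 173 to 347 CPM in the other pBIC libraries. The p53 target Cdkn1a was at 11.8 CPM in pBIC 6 against 0.824 to 3.70 CPM in the others, and Mdm2 at 142 against 52.1 to 99.1 CPM.

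Some transcripts beside the engineered loci differed: within 100 kb, 1 of 4 genes near Prdm1 and 0 of 4 near Gt(ROSA)26Sor were called in BIC and in pBIC against YC, where 8.87% to 8.88% and 22% of other genes were. The long non-coding RNA gene Gm35028 (chromosome 10, 44418400 to 44424324), 12.9 kb from Prdm1, averaged 0.140 ± 0.127 CPM in YC, 75 ± 60.4 CPM in BIC and 24.1 ± 15.6 CPM in pBIC (log2 fold change 9.10 ± 1.42 and 7.47 ± 1.31 against YC, edgeR adjusted p = 0.0041 and 0.00245). Near Trp53, 4 of 15 genes within 100 kb were called between pBIC and YC: Sat2 (log2 fold change 9.31 ± 1.30), Shbg (8.64 ± 1.59), Gm12308 (6.26 ± 1.52) and Eif4a1 (0.86 ± 0.21, 922 ± 186 CPM against 509 ± 46.4 CPM in YC). Sat2 was also called in BIC against YC (5.403 ± 1.224, edgeR adjusted p = 0.0199), where p53 is not floxed, with 0.791 CPM in BIC, 11.9 CPM in pBIC and 0.0146 CPM in YC on average. Altered transcription around the engineered Trp53 allele is a candidate explanation for such genes. The test of it compared the share of called genes, 26.7% within 100 kb against 22% of all other genes, and did not pass (one-sided Fisher's exact test p = 0.429), which leaves the explanation open. Gt(ROSA)26Sor, the locus often used for reporter and transgene insertion, averaged 6.38 ± 0.804 CPM in YC, 1.23 ± 0.178 CPM in BIC and 0.694 ± 0.119 CPM in pBIC; it overlaps the end of Thumpd3 on the other strand and was counted without strand.

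pBIC 1 carried neither Xist (2.58 CPM) nor a male level of Y-linked transcripts. The hypothesis tested was loss of the Y chromosome in tumour cells of a male mouse. The sum of Ddx3y, Eif2s3y, Kdm5d and Uty was 5.48 CPM, above the highest of the libraries with Xist (0.694) and far below the lowest YC library (393), as a small remainder of cells with a Y chromosome may give. Kdm6a, an X-linked gene that escapes inactivation, was at 52.9 CPM there, beside 57.3 and 62.5 CPM in pBIC 3 and 6, 85.4 to 112 CPM in the pBIC libraries with Xist and 93.4 to 104 CPM in YC, so its level does not follow Xist and decides nothing here. A mixture of cells from different mice was not tested.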
